A study of Homo sapiens with 14 samples.

How the data were processed

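Tumours grown in mice from Z138 cells with a control hairpin or 1 of the SOX11 hairpins were measured on 14 Affymetrix HG-U133 Plus 2.0 arrays. The deposited values were log2 expression values made by RMA, per the submitters' processing notes; the RMA version and the probe definition file are not given in the sources used here. The log2 scale was inferred from the values, which ran from 2.47 to 14.73 with array medians between 5.14 and 5.25. Scanner image files were not used here, and the labels give no batch. No pair of arrays shared more than 0.187% of identical values, and arrays of the same group correlated across probe sets at 0.976 to 0.996.

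Of 54675 probe sets, 62 were controls, 41091 mapped to 1 gene, 1801 to several genes, and 11721 are not named here. Each gene was represented by its single-gene probe set with the highest mean over the arrays, which gave 19775 genes. The 13830 genes above 5 (log2) on at least 4 arrays were tested. Genome positions were not used here. Groups followed the title and the infection field of the labels, since the source field matched the title for 4 of the 14 arrays.

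Limma 3.58.1 in R 4.3.3 fitted 1 mean per group with moderated variances. Knockdown against control was the mean of both hairpin groups minus shControl; each hairpin was also set against shControl and against the other hairpin. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with calls under 0.05. The 25 gene lists, with 504 genes of which 43 were not on a single-gene probe set here, were tested by limma's camera with a preset correlation of 0.01, beside camera with an estimated correlation and limma's fry, adjusted over the lists; fry asks whether a list's genes move on balance one way or, separately, in either direction. Members were also adjusted over the list alone. The comparisons, tests, filters, lists, naming rule and most alternatives were chosen before the data were examined.

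The genes named by rule were SOX11; PDGFA, PAX5, PRDM1, CCND1, CXCR4, PTK2, SOX4 and SOX12; up to 12 genes with the largest rise and up to 12 with the largest fall among those called in knockdown against control and, with the same sign, with each hairpin; up to 5 genes in each direction among those called between the hairpins; and, per list, the 2 members with the smallest p, with up to 2 more where the list was called. Other genes are said to have been named after their values were seen.

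RNA degradation was read as the 3' minus 5' difference of the beta-actin and GAPDH control probe sets. A score of stromal markers was taken as the mean of the endothelial, pericyte, fibroblast and macrophage lists. The host is mouse and the probes are human, so the score is no direct measure of stromal content. Differences of these measures between knockdown and control were tested by exact two-sided permutation over all 1001 splits. The agreement of the hairpins was set beside 100 simulated pairs of unchanged groups that shared the controls, and beside divisions of the 4 controls between the hairpins. Other splits of the arrays were drawn 100 times with the real split included.

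The method was tested on simulated data with 200 changed genes in 10 draws. For knockdown against control, limma recovered 30.6% of genes changed by 0.5 log2 units, 83.0% at 1 and 98.6% at 2, with a mean of 4.8 false calls. The mean number of false calls was 1.6 for shSOX11.1 and 15.7 for shSOX11.3. The simulation treated both hairpin groups alike, so this gap reflects the spread over 10 draws. Limma called 0 genes where none was changed in these draws. Of the other splits of the real arrays, however, 7 made calls in knockdown against control, up to 1520 genes. Camera found a list shifted by 0.5 log2 units in 10 of 10 draws and called a mean of 0.9 other lists. The lists called in the real data had means between -0.18 and 0.20, and recovery at such sizes was not simulated.

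The alternatives were other level filters, other choices of probe set, renewed normalization or centring, trended and robust variances, array weights, fits of the compared groups alone, a stricter threshold, limma's treat against a 1.2-fold change, a replicate block, stromal and GAPDH covariates, other set tests, and leaving out each array. Added after seeing the data were the beta-actin difference as a covariate, leaving out the arrays with a difference above 3, fits within the arrays up to 2 and above 2, and the stromal score without PECAM1 and CYBB.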

Results

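Gene expression was measured on 14 Affymetrix HG-U133 Plus 2.0 arrays. The tumours grew under the skin of immunodeficient CB17-SCID mice from Z138 cells, an established human line of mantle cell lymphoma, a B cell cancer. The cells carried a short hairpin RNA against the transcription factor SOX11, either shSOX11.1 (n = 5) or shSOX11.3 (n = 5), or a control hairpin, shControl (n = 4). SOX11 is a SOXC family factor that most mantle cell lymphomas express and normal B cells lack. The comparisons asked which genes depend on SOX11 in these tumours. The labels do not say whether each array came from a separate mouse, so the p-values measure the spread between these arrays. Both hairpins were compared with the same 4 shControl arrays, so anything particular to those arrays would appear with both hairpins. The number of arrays limits the precision of every value, and array medians lay between 5.14 and 5.25 (log2).

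SOX11 was lower on all 10 knockdown arrays than on all 4 control arrays. Its brightest probe set read 9.17, 9.78, 9.21 and 9.47 (log2) on the control arrays, 7.28, 6.52, 7.55, 7.53 and 8.16 with shSOX11.1, and 7.10, 7.91, 7.70, 7.11 and 7.50 with shSOX11.3. The means were 9.41 ± 0.28 (SD, n = 4), 7.41 ± 0.59 (SD, n = 5) and 7.46 ± 0.36 (SD, n = 5). The log2 fold change of knockdown against control was -1.97 (SE 0.24, 95% interval -2.48 to -1.46, limma adjusted p = 0.00160), a level 3.92 times lower. The other SOX11 probe sets gave -1.90 and -1.97. The source field of the labels matched the title for 4 of the 14 arrays; groups were taken from the title and the infection field, which match each other and the group sizes in the protocol.

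In knockdown against control, 21 genes rose and 24 fell, 45 of 13830 genes tested. FGF9, a secreted fibroblast growth factor, fell from 9.10 ± 0.27 (SD, n = 4) in control tumours by 2.55 log2 units (SE 0.34, limma adjusted p = 0.00381), and its other probe set gave -2.58. CNR1, a cannabinoid receptor, fell by 2.09 (SE 0.26, limma adjusted p = 0.00208) on the probe set used, while its other probe sets gave -0.57, -0.11 and 0.10. The one at -0.11 was above the level minimum on 10 arrays. On the probe set used, CNR1 had means of 5.02 with shSOX11.1 and 5.29 with shSOX11.3, near the level minimum of 5 (log2). The size of its fall is therefore limited by the background. TFEC, a transcription factor related to MITF, rose from 5.13 ± 0.48 (SD, n = 4) by 2.33, a level 5.02 times higher (SE 0.36, limma adjusted p = 0.0101). Its control mean lay near the level minimum of 5 (log2), with 4.51 on shControl replicate 1, so the size of this rise is limited by the background. PECAM1, the adhesion molecule CD31 of endothelial cells, platelets and leukocytes, rose from 8.19 ± 0.09 (SD, n = 4) by 1.27 (SE 0.18, limma adjusted p = 0.00442). Of its other probe sets, 2 gave 1.13 and 1.12, and the other 2 gave 0.31 and 0.05.

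Other genes changed the same way with each hairpin. CRACD, an inhibitor of actin capping protein, fell by 1.82, the formin FMNL2 by 1.76, and ASAP2, an activator of Arf GTPases, by 1.65. AMOTL1, a relative of angiomotin, fell by 0.87 on the probe set used, while another of its probe sets, also above the level minimum on all 14 arrays, gave -0.01. RHOBTB3 fell by 0.99 and MLLT11 by 0.56, and LOC441179 fell by 1.40 with the smallest limma adjusted p of all genes, 6.23e-05. GPR183, an oxysterol receptor that positions B cells in lymphoid tissue, rose by 1.27, and PLAAT4, a phospholipase and acyltransferase, by 0.94. JDP2, a bZIP transcription factor, rose by 0.82, the RNA-binding protein RBM47 by 0.78 with 0.68, 0.09, 0.01 and -0.07 on its other probe sets, PLBD1 by 0.75, and GNPDA1, an enzyme of amino sugar breakdown, by 0.61. GNPDA1 had the largest limma adjusted p of these genes, 0.0118. In knockdown tumours CRACD, FMNL2, RHOBTB3 and LOC441179 lay below the level minimum of 5 (log2) with both hairpins and ASAP2 with shSOX11.3, so the sizes of these falls are limited by the background. With the mean of a gene's probe sets, AMOTL1 and RBM47 kept their direction and were no longer called by limma.

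**Figure D1:**
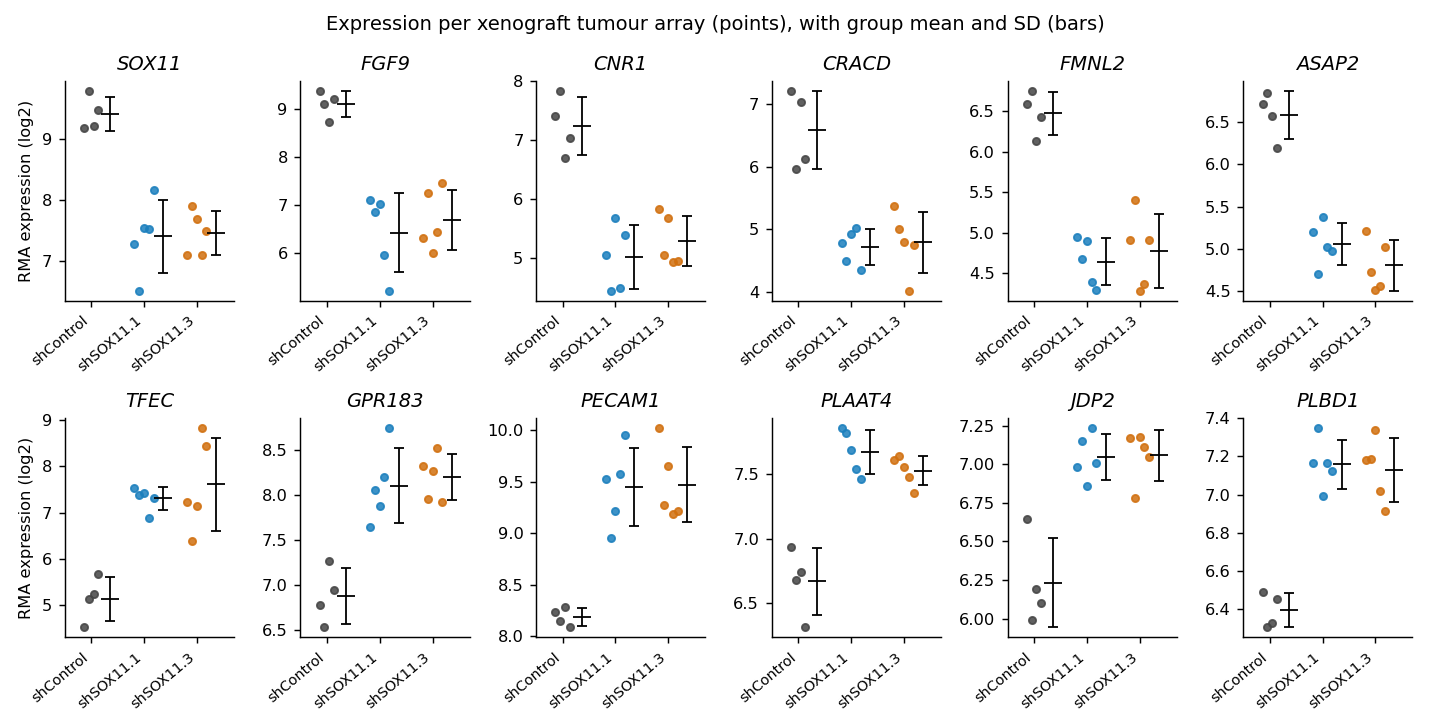
Each panel shows 1 gene, with RMA expression (log2) on the vertical axis and the 3 groups on the horizontal axis; points are arrays, bars are group means with SD, and each panel has its own range. SOX11, FGF9, CNR1, CRACD, FMNL2 and ASAP2 were lower, and TFEC, GPR183, PECAM1, PLAAT4, JDP2 and PLBD1 higher, on all 10 knockdown arrays than on all 4 control arrays.

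Further genes among the 45 are named here after their values were seen. SERPINE2, a secreted protease inhibitor, fell by 2.25 (SE 0.44, limma adjusted p = 0.0499), and the growth factor midkine, MDK, fell by 0.64 (SE 0.10, limma adjusted p = 0.0118). The neuronal membrane protein GPM6A rose by 1.70 (SE 0.27, limma adjusted p = 0.0132), and the chemokine receptor CX3CR1 by 1.72 (SE 0.32, limma adjusted p = 0.0393). SERPINE2, GPM6A and CX3CR1 lost their calls with a score of stromal markers in the fit, with or without PECAM1 and CYBB in the score, and MDK with the full score. SERPINE2 also lost its call without the arrays with a beta-actin difference above 3, and SERPINE2 and CX3CR1 with the replicate block. These genes kept their sign in each of those fits, and a lost call alone does not show that the change was taken up. All 45 genes had the same sign with both hairpins, and 17 differed by at least 2-fold. All 10 knockdown arrays lay beyond all 4 controls for 96 of the 13830 genes, 0.694%, where chance gives 0.200% of unselected genes. Of the 96, 42 were among the 45, which were selected for differing between these arrays. For those 42 the same sign with both hairpins follows from that separation and is no further support.

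A score of stromal marker genes was higher in knockdown tumours by 0.0931 log2 units (exact two-sided permutation p = 0.0320). The score holds the called gene PECAM1 and is read on human probes, so it does not measure stroma of the mouse host directly. In controls 6 of 11 endothelial, 3 of 11 pericyte, 6 of 12 fibroblast and 2 of 10 macrophage markers lay above 6 (log2). With the score in the fit, 11 of the 45 genes passed and no others, 2 higher and 9 lower. FGF9, CRACD, TFEC, GPR183, PECAM1, JDP2, RBM47 and GNPDA1 were not among the 11. All 45 genes kept their sign in that fit, where FGF9 gave -2.33 (SE 0.42), PECAM1 1.14 (SE 0.22), GPR183 1.14 (SE 0.22), CRACD -1.68 (SE 0.32), JDP2 0.78 (SE 0.15) and TFEC 1.87 (SE 0.40), smaller changes with larger errors than without the score. With PECAM1 and CYBB left out of the score, a choice made after seeing the data, the score differed by 0.0530 (exact two-sided permutation p = 0.188), and 22 of the 45 genes passed and no others, 8 higher and 14 lower, PECAM1 included. The beta-actin 3' minus 5' difference, a measure of RNA degradation, ranged from 0.85 to 3.71 (log2) and differed between knockdown and control by 0.03 (exact two-sided permutation p = 0.958). With that difference in the fit, also chosen after seeing the data, 127 genes passed, 76 higher and 51 lower, all 45 among them. Within the 7 arrays with a difference up to 2, 27 genes passed, and within the 7 arrays above 2 limma called 0. SOX11 gave -1.93 and -1.95. All 45 genes kept their sign in both, but they had been selected on these same arrays. For 42 of the 45, all 10 knockdown arrays lay beyond all 4 controls, which fixed the sign in any part of the arrays. Without shSOX11.1 replicate 5 and shSOX11.3 replicate 2, the arrays above 3, 45 genes passed, 35 of them shared with the full set of arrays.

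The count of 45 genes fell when single arrays were left out. It was 17, 23, 19 and 25 without shControl replicate 1, 2, 3 and 4. For genes changed, knockdown against control, it was 26, 28, 25 and 29 without shSOX11.1 replicate 1, 2, 3 and 4, and 29 without shSOX11.3 replicate 2 or without shSOX11.3 replicate 5. TFEC lost its call without shControl replicate 1 (limma adjusted p = 0.0693), with a log2 fold change of 2.12. GNPDA1 lost its call without shControl replicate 2 (limma adjusted p = 0.0572) and without shControl replicate 3 (limma adjusted p = 0.0653), with log2 fold changes of 0.61 and 0.53.

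None of the genes fixed in advance for their ties to SOX11 or to the disease passed the limma test, SOX11 itself aside. PDGFA, an angiogenic growth factor, differed by -0.04 (SE 0.35, 95% interval -0.78 to 0.70). PAX5, which maintains B cell identity, differed by -0.26 (SE 0.42, interval -1.15 to 0.64), and PRDM1, a regulator of plasma cell fate, by -0.21 (SE 0.27, interval -0.78 to 0.37). Cyclin D1, CCND1, differed by 0.02 (SE 0.19), with 0.65 on its other probe set, and the chemokine receptor CXCR4 by -0.03 (SE 0.09). The SOXC relatives SOX4 and SOX12 differed by -0.20 (SE 0.12) and 0.13 (SE 0.28). PTK2 was below the level minimum and was not tested.

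Of 25 gene lists, camera with its preset correlation called 5 in knockdown against control, 4 higher and 1 lower, and none of these calls held with an estimated correlation. The 22 measured genes of oxidative phosphorylation, the mitochondrial respiratory chain, were all positive, with a mean of 0.17 (camera adjusted p = 0.000166; adjusted p = 0.295 with an estimated correlation). Limma called 0 of them over all genes and 0 adjusted over the list alone. NDUFA2 gave 0.30, COX5B 0.29, NDUFB5 0.29 and COX6A1 0.15. By fry the adjusted p was 0.129 for change one way and 0.423 for change in either direction. The 15 interferon response genes had a mean of 0.20 (camera adjusted p = 0.00497; adjusted p = 0.226 with an estimated correlation), with 0 called by limma over all genes and 2 higher adjusted over the list alone, OAS1 at 0.70 (SE 0.15) and MX2 at 0.58. IRF9 gave 0.23 and USP18 0.40. By fry the adjusted p was 0.109 for change one way and 0.0181 for change in either direction. With the stromal score in the fit the interferon call ended (camera adjusted p = 0.197).

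The 19 measured mantle cell lymphoma genes had a mean of -0.18 (camera adjusted p = 0.00497, or 0.0831 with an estimated correlation). By fry the adjusted p was 0.0414 for change one way and 0.305 for change in either direction. Limma called 0 of them over all genes and 0 adjusted over the list alone; FNBP1L gave -0.80, NREP -0.40, BCL2 -0.36 and CNN3 -0.27. The 19 plasmacytic differentiation genes had a mean of 0.18 (camera adjusted p = 0.0162, or 0.223 with an estimated correlation). By fry the adjusted p was 0.129 for change one way and 0.138 for change in either direction. Limma called 0 over all genes and 1 higher adjusted over the list alone, SLAMF7, a surface receptor of plasma cells, at 1.45 (SE 0.35) from a control mean of 4.88, below the level minimum; CAV1 gave 0.49, SSR4 0.20 and IRF4, a factor plasma cells need, -0.49. The plasmacytic call ended without shControl replicate 2 (camera adjusted p = 0.0878) and without shControl replicate 3 (camera adjusted p = 0.0519), with list means of 0.13 and 0.19.

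Of the 23 measured B cell identity genes, 1 fell over all genes and 2 adjusted over the list alone, with a mean of -0.10 (camera adjusted p = 0.430). CD24, a surface glycoprotein of immature B cells, fell by 2.39 (SE 0.38, limma adjusted p = 0.0123), and EBF1, a B lineage transcription factor, gave -0.85 (SE 0.22). The CD24 call ended without shControl replicate 1, 2 or 3 (limma adjusted p = 0.0748, 0.0614 and 0.0586), with log2 fold changes of -2.24, -2.39 and -2.40, and EBF1 passed over all genes without shSOX11.3 replicate 4 (limma adjusted p = 0.0412). Of 19 BCR signalling genes, FCGR2B, an inhibitory Fc receptor, rose by 0.85 (SE 0.15, limma adjusted p = 0.0343), 1 over all genes and 1 adjusted over the list alone; RASGRP3 gave -0.21 and the list mean was 0.07 (camera adjusted p = 0.653). The FCGR2B call ended without shSOX11.1 replicate 1, 2 or 3 (limma adjusted p = 0.0620, 0.0615 and 0.0670), without shSOX11.3 replicate 5 (0.0616) and without shControl replicate 1, 2 or 4 (0.150, 0.169 and 0.125), with log2 fold changes between 0.78 and 0.86. The 13 class II antigen presentation genes had a mean of 0.09 (camera adjusted p = 0.230), 0 called by limma over all genes and 1 higher adjusted over the list alone, CTSS at 0.47; HLA-DQA1 gave 0.32.

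Of the 14 measured angiogenic factors, 1 fell over all genes, and 1 fell and 1 was higher adjusted over the list alone. The Notch ligand JAG1 fell by 0.95 (SE 0.16, limma adjusted p = 0.0136), and ADM, the vasodilator adrenomedullin, gave 0.71. The list mean was -0.01 and its median 0.04 (camera adjusted p = 0.764). By fry the adjusted p was 0.868 for change one way and 7.40e-05 for change in either direction. The fry values include JAG1, the only member called over all genes, and are not given without it. The JAG1 call ended without shControl replicate 1, 2, 3 or 4 (limma adjusted p = 0.0693, 0.0764, 0.0512 and 0.0688), with log2 fold changes of -0.92 or further below 0 in each. With either stromal score in the fit JAG1 and FCGR2B lost their calls and kept their sign. Of 11 endothelial markers, PECAM1 rose and 10 did not pass, 1 over all genes and 1 adjusted over the list alone; TIE1 gave -0.50. The endothelial mean was 0.07 and the median -0.01 (camera adjusted p = 0.665). By fry the adjusted p was 0.597 for change one way and 3.31e-06 for change in either direction. The fry values include PECAM1, the only member called, and are not given without it, so they show no change of the other markers.

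The 10 measured macrophage and myeloid markers had a mean of 0.17 (camera adjusted p = 0.00837; adjusted p = 0.292 with an estimated correlation). Limma called 0 over all genes and 1 higher adjusted over the list alone, CYBB, an NADPH oxidase subunit, at 0.53 (SE 0.12), while another of its probe sets, above the level minimum on 12 arrays, gave 0.10 (SE 0.09); MSR1 gave 0.43, MARCO 0.20 and FCER1G 0.17. By fry the adjusted p was 0.129 for change one way and 0.00443 for change in either direction. The camera call ended without shSOX11.1 replicate 5 (camera adjusted p = 0.0617) and without shControl replicate 1 (camera adjusted p = 0.107), with list means of 0.14 and 0.13, and also without both arrays with a beta-actin difference above 3 (camera adjusted p = 0.0702). Limma called 0 genes, over all genes and adjusted over the list alone, in the pericyte, fibroblast, and skin, fat and muscle lists. The 11 pericyte markers had a mean of 0.00, a median of -0.02 and a test direction downward (camera adjusted p = 0.630; KCNJ8 0.18, CSPG4 -0.12). The 12 fibroblast markers had a mean of 0.13 (camera adjusted p = 0.314; COL1A2 0.37, BGN -0.15), and the 5 skin, fat and muscle markers 0.12 (camera adjusted p = 0.630; ACTA1 0.31, KRT10 0.43). The 9 T and NK cell markers had a mean of 0.01 and a median of 0.08 with a downward test (camera adjusted p = 0.665), 0 called over all genes and 1 lower adjusted over the list alone, LCK at -0.50; CD7 gave -0.19. The arrays read human probes, and mouse RNA reaches them only by cross-hybridisation.

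The remaining lists were not called, and limma called 0 of their members over all genes. Adjusted over the list alone, 1 gene was higher in hypoxia response (BNIP3L 0.54), p53 targets (SESN1 0.52) and adhesion and migration (SELPLG 0.72, but 0.09 on its other probe set, also above the level minimum on all 14 arrays), and 0 in the others. SESN1 passed over all genes without shControl replicate 4 (limma adjusted p = 0.0348). Hypoxia response had a mean of 0.07 (camera adjusted p = 0.274; BNIP3 0.47), and p53 targets 0.13 (camera adjusted p = 0.191; TP53I3 0.24). Adhesion and migration had a mean of 0.02 with a downward test (camera adjusted p = 0.691; GNA13 -0.22). Cell cycle had a mean of -0.04 (camera adjusted p = 0.314; BUB1 -0.27, E2F1 -0.20), and NF-kB targets -0.05 (camera adjusted p = 0.274; IER3 -0.32, TNFAIP3 -0.31). The BCL2 family had a median of -0.02 (camera adjusted p = 0.630; PMAIP1 -0.35). The unfolded protein response had a mean of 0.05 (camera adjusted p = 0.630; DNAJC3 0.25, ASNS -0.23).

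Cholesterol synthesis had a mean of 0.07 (camera adjusted p = 0.357; FDPS 0.26, INSIG1 0.22), and ribosomal proteins 0.02 (camera adjusted p = 0.738; RPL18 0.13, RPLP2 -0.09). MYC targets and ribosome biogenesis had a mean of -0.03 and a median of 0.01 (camera adjusted p = 0.630; PPAT -0.23, POLR1B -0.14). The neural SOXC-linked genes had a mean of -0.12 (camera adjusted p = 0.206; MARCKSL1 -0.79, DBN1 -0.53).

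**Figure D2:**
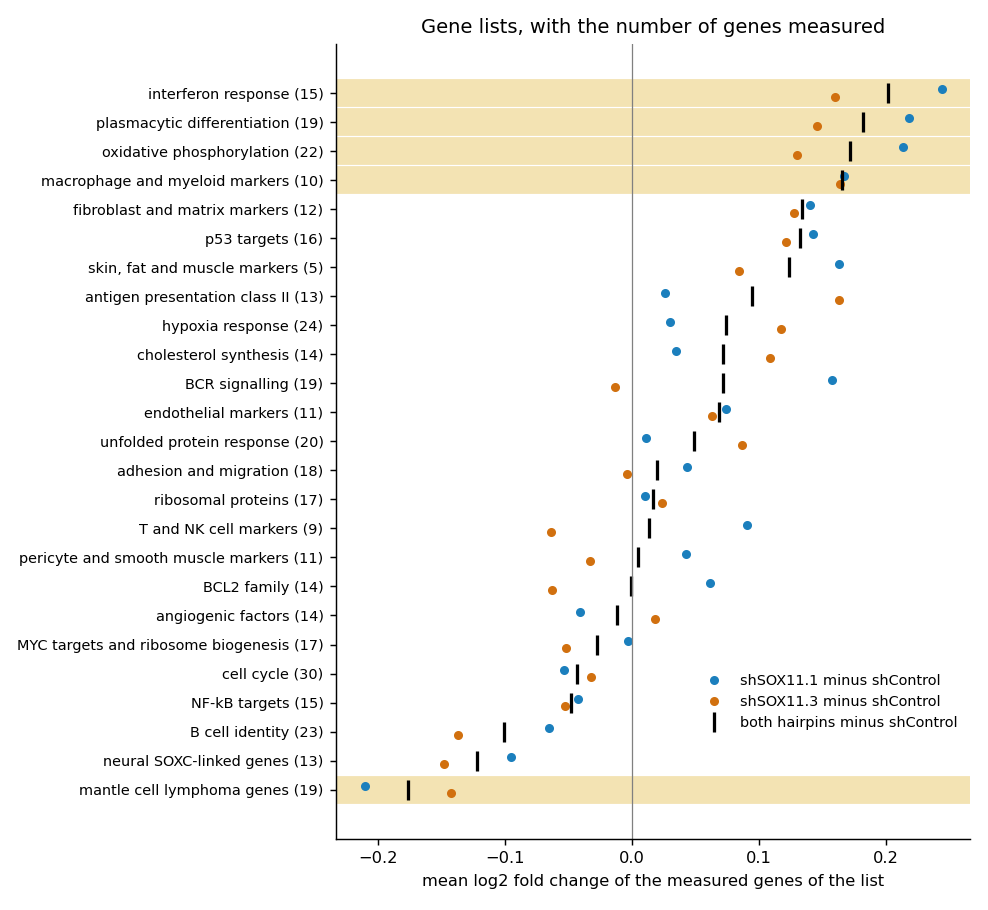
The mean log2 fold change of each of the 25 gene lists is on the horizontal axis, with dots for each hairpin against control and a black bar for both; shaded lists were called by camera with its preset correlation. Oxidative phosphorylation had a mean of 0.17 and mantle cell lymphoma genes a mean of -0.18 in knockdown against control.

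With shSOX11.1 against control, 26 genes passed, 12 higher and 14 lower. SOX11 fell by 2.00 (SE 0.27, limma adjusted p = 0.00514). FGF9 fell by 2.68 and CD24 fell by 2.61 (limma adjusted p = 0.0244), while TFEC rose by 2.18 and PECAM1 by 1.26. Camera called 5 lists: oxidative phosphorylation (adjusted p = 4.77e-05; adjusted p = 0.299 with an estimated correlation), interferon response (adjusted p = 0.00119; adjusted p = 0.212 with an estimated correlation), mantle cell lymphoma genes (adjusted p = 0.00366; adjusted p = 0.0712 with an estimated correlation), macrophage and myeloid markers (adjusted p = 0.0246; adjusted p = 0.346 with an estimated correlation) and plasmacytic differentiation (adjusted p = 0.0392; adjusted p = 0.241 with an estimated correlation). The gene count was 12, 13, 16 and 12 without shControl replicate 1, 2, 3 and 4, and 16, 14, 16 and 17 without shSOX11.1 replicate 1, 2, 3 and 4. In the count of genes changed, shSOX11.1 against shControl, the stromal score gave 11 and the beta-actin difference in the fit 80.

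With shSOX11.3 against control, 26 genes passed, 10 higher and 16 lower. On simulated data with 200 changed genes the mean number of false calls was 15.7 here and 1.6 for shSOX11.1. The simulation treated both hairpin groups alike, so this gap reflects the spread over 10 draws and not a trait of shSOX11.3. SOX11 fell by 1.94 (SE 0.27, limma adjusted p = 0.00948), ASAP2 fell by 1.78, FGF9 fell by 2.42 and JAG1 fell by 1.07 (limma adjusted p = 0.0196), while TFEC rose by 2.48 and PECAM1 by 1.28. Camera called 6 lists: oxidative phosphorylation (adjusted p = 0.0284; adjusted p = 0.521 with an estimated correlation), class II antigen presentation and macrophage markers (both adjusted p = 0.0284; adjusted p = 0.409 with an estimated correlation), and plasmacytic differentiation, hypoxia response and mantle cell lymphoma genes (each adjusted p = 0.0477; adjusted p = 0.409 with an estimated correlation). The gene count was 10, 11, 11 and 15 without shControl replicate 1, 2, 3 and 4, 8 with the stromal score and 59 with the beta-actin difference in the fit.

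The hairpins shared 18 genes that changed the same way with each of them, 8 higher and 10 lower, SOX11 among the lower. Lists drawn independently would share 0.00868 higher and 0.0162 lower genes, but the comparisons use the same controls and are not independent. A set of 100 simulated pairs of unchanged groups against the same controls shared 0. That sets the count against no change at all. It does not show how much of the overlap among called genes the shared controls give. The shared count was 8, 8, 10 and 9 without shControl replicate 1, 2, 3 and 4. Across the 13830 genes, which are not independent replicates, the log2 fold changes of the hairpins had a Pearson r of 0.62 and a Spearman rho of 0.50. The hairpins share their controls, and the simulated unchanged groups gave a mean r of 0.571, from -0.711 to 0.974. The real r lay well inside that range. The same sign was found for 66.4% of genes, against a mean of 70.5% in the simulated groups. With the controls divided between the hairpins, r ranged from -0.315 to 0.420, with a median of 0.271.

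**Figure D3:**
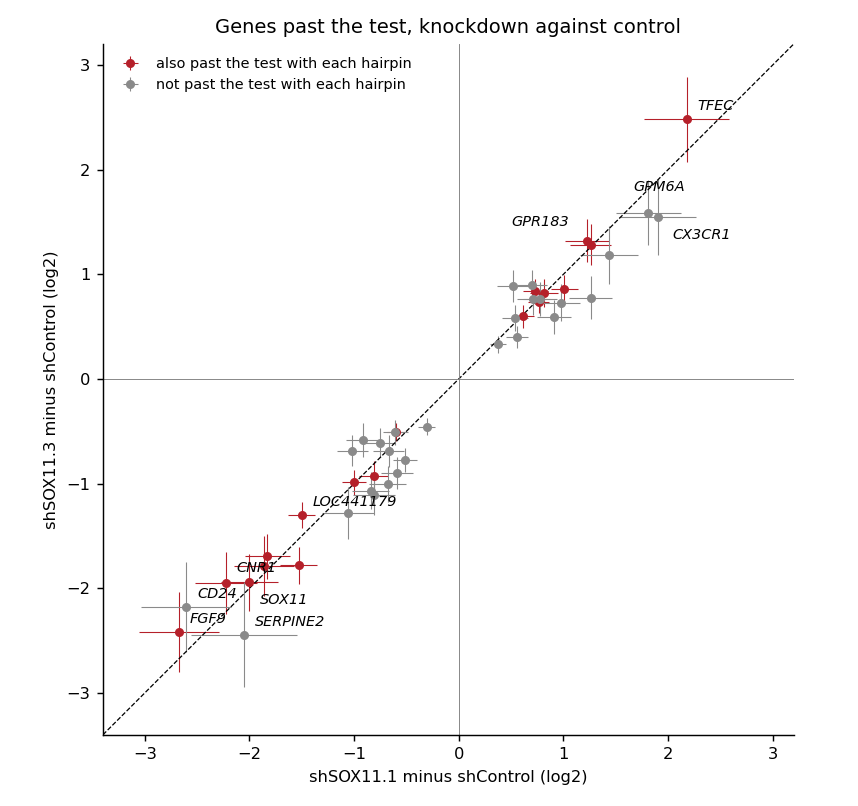
The log2 fold changes of the 45 genes called in knockdown against control are plotted for shSOX11.1 on the horizontal axis and shSOX11.3 on the vertical axis, with SE; red points are the 18 genes also called with each hairpin, grey points the others, and the dashed line marks equal values. All 45 genes, selected on these same arrays, had the same sign with both hairpins. For 42 of them this follows from all 10 knockdown arrays lying beyond all 4 controls.

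Between the hairpins themselves, limma called 0 genes, with 820 at an unadjusted p under 0.05 and a smallest adjusted p of 0.834. SOX11 differed by -0.06 (SE 0.25) between shSOX11.1 and shSOX11.3. Camera called 0 lists, with 3 at an unadjusted p under 0.05, and 0 with an estimated correlation or by fry. The smallest unadjusted camera p was that of class II antigen presentation, 0.00480, which did not pass after adjustment.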

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

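The tests chosen only after the result was seen were those of RNA quality against the 45 genes, of the share of a change that the beta-actin difference takes up, of endothelial cells against PECAM1, and of the splits with the beta-actin difference in the fit, as were the use of CYBB as reference in the macrophage test and its condition that genes lie above 6 (log2).

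The first pattern is the 45 genes called in knockdown against control. Chance could not be excluded as the source of a count this large: 5 of 100 splits of the arrays, the real one included, called as many, and the highest other called 1520. The 4 other splits parted the arrays by beta-actin difference, with group differences of 1.15 to 1.39 against 0.03 in the real split, which points to a structure of the arrays in RNA quality, and they called 0 genes by limma with that difference in the fit. In that fit the real split called 127 and the highest other 174, with 2 of 100 as large. Chance is a less likely source there but is not excluded, since another split called more and the test was added afterwards. In the real split that fit moved none of the log2 fold changes of the 45 genes by more than 0.626%, and 100% of them were still called. Neither is a test of degradation as their source, since knockdown and control differed in beta-actin by 0.03 and the fit could move little. That 0.03 is an average over hairpin groups on opposite sides of control. The beta-actin means were 2.06 ± 0.92 (SD) for shControl, 1.82 ± 1.18 for shSOX11.1 and 2.35 ± 0.99 for shSOX11.3. The single hairpins were thus less balanced against control, and the spread within groups was wide. The GAPDH difference was 0.02 (exact permutation p = 0.862). Quality that neither control reads, and an effect of the SOX11 hairpins, were not tested further.

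The 26 genes of shSOX11.1 (2 of 100 splits as large, highest other 1202) met the bound set beforehand, under 5 of 100. So did the 26 genes of shSOX11.3 (3 of 100, highest other 687). The 18 genes shared by both hairpins met it too (1 of 100, the real one, highest other 0). Chance is a less likely source of these counts. It is not excluded for the 26 genes of either hairpin, where other splits called far more. Nor can chance be excluded for the 5 lists (5 of 100, highest other 7), and 64 of the other splits called at least 1 list. Between the hairpins the real count was 0 and the highest other 15, so all 100 splits were as large.

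The second pattern is PECAM1, higher in knockdown tumours by 1.27. If endothelial cells of the host were the source, the other endothelial markers should be higher too, but the median of the other 10 was -0.0194 (SD 0.17). Only 4 of these lay above 6 (log2), FLT1 at -0.12, ENG at -0.04, ROBO4 at -0.00 and EGFL7 at -0.01, and human probes read mouse RNA poorly, so host cells and the tumour cells as the source cannot be told apart. A change in PECAM1 within the lymphoma cells may be an explanation and was not tested.

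The third pattern is the macrophage and myeloid list, with a mean of 0.17. The beta-actin difference in the fit moved its mean by 1.00%, and the call held there (camera adjusted p = 0.0250). Neither is a test of degradation as the source, since knockdown and control hardly differed on average in that measure. The held call was nevertheless set beforehand as one. The call ended without the arrays above 3 (camera adjusted p = 0.0702). For macrophages of the host, 9 genes they express strongly had a median of 0.0872 (SD 0.11) against 0.53 for CYBB (0.10 on another of its probe sets), below it by more than the spread. As written beforehand, without a condition on level, this speaks against host macrophages, but the bound was wrong for these data: no list member passed over all genes, so CYBB was taken instead, and only AIF1 of the 9 lay above 6 (log2), at 0.12, where the human probes could read mouse RNA little; host macrophages and the tumour cells cannot be told apart. The oxidative phosphorylation list also kept its call with the beta-actin difference in the fit (camera adjusted p = 2.25e-05), which moved its mean by 0.431%. With knockdown and control hardly apart on average in that measure, this is no test of degradation as its source either.

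Single arrays far from the others of their group were found in 23 of 333 groups of values, 6.91%, where chance gives about 1 in 20; 10 lay on shSOX11.1 replicate 5, the array with the largest beta-actin difference, 3.71, and 4 on shSOX11.3 replicate 4. On shSOX11.1 replicate 5, PDGFA read 8.59 (log2), HLA-DQA1 11.91 and MSR1 6.93, above the other arrays, and CCND1 12.30 and DBN1 7.07, below them. On the same array the list means were 9.81 for plasmacytic differentiation, 8.46 for adhesion and migration and 8.15 for mantle cell lymphoma genes, below the others, and 6.42 for endothelial and 6.03 for macrophage markers, above them. On shSOX11.3 replicate 4, PRDM1 read 7.27, IRF4 10.38, GNA13 11.52 and BCL2 9.72, all below the others. LOC441179 read 4.32 on shSOX11.1 replicate 3, above the others, AMOTL1 5.63 on shSOX11.1 replicate 4 and LCK 7.86 on shSOX11.3 replicate 2, below them. Among controls, replicate 1 lay above the others for MX2, 7.73, and for the unfolded protein response list, 9.91, and replicate 2 for CXCR4, 13.04. Replicate 3 lay below the others for ASNS, 11.16, and HLA-DQA1, 10.74, and replicate 4 for TNFAIP3, 10.58.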

How the results depend on the processing

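The beta-actin covariate, the fit without arrays above 3 and the stromal score without PECAM1 and CYBB were chosen after seeing the data. SOX11 kept its direction and call under every alternative run except the fit within the 7 arrays with a beta-actin difference above 2, where limma called 0 genes and SOX11 gave -1.95; the count between the hairpins was 0 in each alternative that gave one. Of the named genes and lists called, 587 gene values and 140 list values kept their call and direction, and 46 and 24 lost the call. Signal near the background limits the dim stromal markers. Except where fewer arrays or a stricter threshold show it, the cause was not tested.

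The counts are for genes changed, knockdown against control (45), genes changed, shSOX11.1 against shControl (26), genes changed, shSOX11.3 against shControl (26), and genes changed the same way by both hairpins (18), then of lists in knockdown against control (5) and in the 3 other comparisons (11). Adjusted p under 0.01 gave 16, 10, 6 and 6 genes and 3 lists in the other comparisons; treat gave 14, 8, 5 and 5 genes and no value for lists, and neither gave a value for the correlation of the hairpins. The stromal score gave 11, 11, 8 and 8 genes and 3 and 5 lists; without PECAM1 and CYBB it gave 22 and 14 genes for knockdown and shSOX11.1 and 7 lists in the other comparisons. The beta-actin difference gave 127, 80, 59 and 34 genes and 17 lists in the other comparisons. For shSOX11.1 the mean of probe sets gave 16, array weights 111 and the GAPDH difference 51. The compared groups alone gave 17 for shSOX11.3 and 10 shared. The filter above 6 gave 7 lists and the largest interquartile range 4 in the other comparisons, and every probe set on its own gave 10 and 18 lists. Estimated correlation gave 0 and 0 lists, and fry 1 and 0; fry for change in either direction called 4 lists in knockdown against control, 3 for shSOX11.1, 2 for shSOX11.3 and 0 between the hairpins. The replicate block gave 26 genes in knockdown against control, 10 for shSOX11.3 and 9 shared; residuals of arrays with the same number correlated at -0.455 to 0.765, with a mean of 0.215 against -0.0519 for different numbers, 8 of 13 pairs were above 0.1, and 4 of 14 arrays correlated best with their own number. The labels give the number no shared mouse or day and not every pair was above 0.1, so the arrays were not treated as paired, and a partial sharing by number stays open.

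With single arrays left out, the ranges were -2.07 to -1.85 for SOX11, 17 to 43 genes for knockdown against control, 12 to 30 for shSOX11.1, 10 to 29 for shSOX11.3, 8 to 18 shared, 0 to 0 between the hairpins, 4 to 5 lists, 3 to 13 lists in the other comparisons, and 0.449 to 0.722 for the correlation of the hairpins. The lists in the other comparisons numbered 4, 3 and 7 without shControl replicate 2, 3 and 4. That correlation, 0.62, was 0.319, 0.137 and 0.223 with controls 1 and 2, 1 and 3, and 3 and 4 given to shSOX11.1, and -0.315, reversed, with controls 2 and 4.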

Other observations

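With the beta-actin difference in the fit, a test chosen only after the result was seen, further genes passed that are named here after their values were seen; the lysosomal test was set before its result was seen. FUCA1 and RNASET2, enzymes of the lysosome, rose by 0.82 (SE 0.11, limma adjusted p = 0.00284) and 0.61 (SE 0.09, limma adjusted p = 0.00474). ETFB, a part of the electron transfer flavoprotein, rose by 0.59 (SE 0.10, limma adjusted p = 0.0133). The insulin-like growth factor binding protein IGFBP2 fell by 1.03 (SE 0.21, limma adjusted p = 0.0307). Without the beta-actin difference, FUCA1 gave 0.81 (SE 0.19, limma adjusted p = 0.142) and RNASET2 0.60 (SE 0.13, limma adjusted p = 0.0866), and neither passed.

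The hypothesis that other lysosomal genes may be higher as a group was tested on 26 measured genes of a list that leaves out FUCA1 and RNASET2. This test was made without the beta-actin difference in the fit. The list had a mean of 0.17 and a median of 0.15, with 20 positive genes (camera p = 0.00988 with the preset correlation), which goes with the hypothesis. The result was lost with an estimated correlation (p = 0.240) and by fry (p = 0.208). Without that difference limma called 0 of the 26 over all genes and 1 adjusted over the list alone. This was NPC2, a cholesterol carrier of the lysosome, at 0.43 (SE 0.11). With the beta-actin difference in the fit, the list member MAN2B1 passed over all genes, at 0.53 (SE 0.12, limma adjusted p = 0.0497).

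Within groups, the first component of the spread took 53%, and its correlation with the beta-actin difference over the 14 arrays was 0.942 in size by Pearson (permutation p = 1e-05) and 0.943 by Spearman (permutation p = 1e-05), the smallest p that 100000 permutations can give. Without the 2 arrays farthest from the median the Pearson value was 0.915.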
